A study of Mus musculus with 4 samples.

How the data were processed

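The study compared ventricles, with the septum, of mice that had 1 kidney removed and received deoxycorticosterone acetate (DOCA), a mineralocorticoid hormone, for 5 weeks. All mice ate food with 0.5 mg Na per g. The high-salt mice drank 1% NaCl and the low-salt mice drank tap water. Total RNA of 1 high-salt and 1 low-salt mouse was labelled with Cy3 and Cy5, reverse transcribed with oligo(dT) and hybridised together on printed cDNA arrays, per the labels' protocols. Foreign control RNA was added to the labelling reactions, per the labels' protocols, in amounts not given there. There were 6 mice in 3 pairs and 4 arrays. Arrays 1 and 2 carried Cy3 on the high-salt RNA and arrays 3 and 4 carried Cy5 on it. Arrays 2 and 4 held the same 2 mice with the dyes exchanged. These 2 arrays are technical repeats and were averaged first, so n was 3 pairs. No counts or intensities were used here, and the number of arrays limits the precision.

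The authors deposited 1 log ratio per feature and array, taken here as a log2 ratio of the 2 dyes. The base of the logarithm, the background correction, the normalization and the direction of the ratio are not given in the sources used here. The deposited log2 ratios had medians of 0.01, -0.0008, -0.0062 and -0.0061 on arrays 1 to 4, and they ran from -7.35 to 5.14. Base 2 is an assumption, and with another base the log2 ratios would scale by 1 factor while signs and p-values would stay. The table had 17664 features, of which 17207 had a value on all 4 arrays and 457 had none on any array. No missing-value rule could therefore alter a fit.

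The relative direction of the arrays was uncertain. Before the data were examined, the following rule was set. Arrays 2 and 4 share both mice, so differences between individual mice should make their correlation the highest of the 4 correlations between arrays of opposite dye if the authors had already turned the swapped arrays, and the lowest if not. Otherwise no direction was to be given. Over all 17207 features the rule did not decide: r was -0.41 for arrays 2 and 4, against -0.34, -0.56 and -0.61 for the other opposite pairs. After the values had been inspected, including that several collagen clones kept 1 sign on all 4 arrays, 736 features were left out. They lie at 23 print positions that recur in all 32 print blocks and have no gene name in any block, and they were taken as control spots, which the labels mention without giving positions. Over the remaining 16471 clones r for arrays 2 and 4 was -0.07, the highest of the 4, but only just above the -0.08 of arrays 1 and 4. The difference of arrays 2 and 1 correlated with that of arrays 4 and 3 at r = 0.05 (bootstrap SE 0.018 over 8106 genes, 1000 resamples), and at -0.0071 (SE 0.011) over all features. Genes are not independent, so these SEs are too small. The table was read as already turned, with positive values meaning higher in high salt, as the array titles word the comparison. This direction is likely and not settled. This rule did not say which features to use, and leaving out the recurring ones is a choice made after seeing the data. Counts and called lists are also given with the arrays turned.

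Gene names came from a table that pairs features with the platform annotation. Of all features, 12563 had 1 symbol, 412 had several and 4689 had none there. Gene IDs of 12555 of those with 1 symbol were found in the RefSeq gene table of assembly GRCm38.p6, 8 were not found, and 0 symbols needed an update. No coordinates are given because the deposited values name no genome build. Clones of 1 symbol were averaged per gene (avereps), which gave 8106 genes, 5255 of them from 1 clone. Clones with several symbols were not named.

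Per-pair log ratios were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes) and adjusted by Benjamini-Hochberg at 0.05. The mean over the pairs cancels a gene-specific dye effect, since pair 1 and pair 3 had opposite orientations and pair 2 had both, but such an effect stays in the spread. Without pair 1 or pair 3, or with 1 array of pair 2, the orientations are unbalanced and the effect does not cancel. Gene lists were fixed before the data were examined and covered cardiac, metabolic, matrix, corticosteroid, stress, growth and inflammation genes and markers of other cell types that ventricle pieces can hold. The 24 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, and again with camera at an estimated correlation and with fry. A skeletal muscle list had too few measured members. Heart and body weights came from the labels and were compared by a two-sided exact permutation test of the 20 assignments of 3 mice against 3.

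The genes named were chosen by a rule set at the same time. Among genes with 1 sign on all 4 arrays it took the 12 largest in each direction past the adjusted threshold, filled to 12 by the smallest unadjusted p where fewer passed. None passed, so all 24 were filled in this way. Up to 4 members of each list with the smallest unadjusted p were added, with Nppa, Nppb, Myh7, Acta1, Col1a1, Col3a1 and Sgk1, of which Nppa, Myh7 and Acta1 were not among the genes with a singly named clone. This gave 106 genes. A further 7, Egr1, Atf3, Ppp1r15a, Fos, Junb, Ciart and Arntl, were chosen after their values were seen.

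A dye effect was to be fitted on 4 arrays with animal pair as a block whose correlation is estimated. limma gave no estimate for 4 arrays in 3 blocks, so the correlation was set to 0.5 in its place, a value chosen after the data were seen. Alternatives set beforehand were median centring, a common spread, either array of pair 2 alone, leaving out each pair, robust eBayes, the other reading of the table, singly named clones, genes with 1 clone, the other list tests and Spearman's rho. Fits with a dye term, the return of the recurring unnamed features, and lists without shared members were added after seeing the data.

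The fits were tested on simulated data for 8106 genes, of which 67, 67 and 66 were changed by 0.5, 1 and 2 on the log2 scale. The simulated noise was redrawn once, from limma's fitted variance prior, because the spread of the first version was too uniform. With the measured dye effects included, the 3-pair fit called 0 of 67 genes changed by 0.5 on the log2 scale, 39 of 67 changed by 1 and 59 of 66 changed by 2, with 1 unchanged gene called. Without dye effects it called 34, 62 and 64 of them. A list of 18 genes shifted by 0.3 was called by camera with the preset correlation in both simulations, and 0 of the 22 lists without its genes were. With an estimated correlation the shifted list was not called, at an adjusted p of 0.271 without and 0.61 with dye effects. Noise was drawn independently for each gene. These list results therefore cannot show how the preset correlation behaves where genes of a list vary together. Figures were drawn with matplotlib 3.10.9.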

Results

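Gene expression was measured in heart ventricles of 6 male DOCA-treated mice, 3 on high salt and 3 on low salt, with each array setting 1 high-salt heart against 1 low-salt heart. DOCA drives the kidney to retain sodium, and with salt in the drinking water it is a standard model of hypertension with cardiac enlargement. The 4 arrays covered 3 animal pairs, with pair 2 measured on 2 arrays of exchanged dye. Values for 16471 clones and 8106 named genes entered the comparison. Whether salt intake altered cardiac gene expression in these mice was the question of the design.

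The hearts of the high-salt mice were heavier. Heart weight was 126 ± 5.69 mg in high salt and 108 ± 1.0 mg in low salt (mean ± SD, n = 3 each), a difference of 17.0%. The cardiac weight index, heart weight over body weight, was 4.83 ± 0.104 mg/g against 4.04 ± 0.031 mg/g, a difference of 19.5%. The lowest high-salt index, 4.71 mg/g, lay above the highest low-salt index, 4.07 mg/g. Both differences had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allows, and 0.15 after adjustment over 3 measures. Body weight was 26.2 ± 0.651 g against 26.7 ± 0.265 g (exact permutation p = 0.3, two-sided).

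Signed expression values below are log2 ratios read as high over low salt. That direction is likely from the array titles, but the correlation rule set to decide whether swapped arrays had been turned did not decide over all features, and the reading was adopted after the values had been inspected. Base 2 is assumed. With the arrays turned, no gene list passed the threshold, so each list result depends on this reading. So do the sizes and order of the genes: with arrays 1 and 2 turned against 3 and 4, the means of the 24 genes described next lay between -0.27 for Hmox1 and 0.19 for Vdac1.

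Among the 12 positive genes chosen by rule, each above 0 on all 4 arrays, were genes of the extracellular matrix. Col3a1, a fibrillar collagen chain, had a mean log2 ratio of 1.04 ± 0.19 (SD, n = 3 pairs), and Col1a2, a chain of type I collagen, 1.03 ± 0.20. Tnc, the matrix glycoprotein tenascin C, stood at 0.74 ± 0.11. Hmox1, the heme-degrading enzyme heme oxygenase 1, stood at 1.78 ± 0.39, and Lcn2, an iron-siderophore-binding secreted protein, was at 1.30 ± 0.29. Tmsb4x, an actin-sequestering peptide, stood at 0.73 ± 0.14, Bmp4, a secreted growth factor, at 0.56 ± 0.081, and Dkk3, a secreted glycoprotein of the Dickkopf family, at 0.49 ± 0.047. Golim4, Itm2a, Nrep and Setdb2 completed the 12 positive genes, between 0.51 for Nrep and 1.32 for Setdb2. None of these genes passed the adjusted threshold.

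The 12 negative genes, each below 0 on all 4 arrays, included inflammatory and mitochondrial ones. S100a9, a calcium-binding protein of neutrophils and other myeloid cells, had a mean log2 ratio of -1.42 ± 0.45 (SD, n = 3 pairs), Zfp36, which promotes decay of cytokine mRNA, -1.30 ± 0.35, and Irf1, an interferon-regulated transcription factor, -1.26 ± 0.26. Vdac1, the main channel of the outer mitochondrial membrane, stood at -1.13 ± 0.25. Hadh and Ech1, enzymes of mitochondrial fatty acid oxidation, stood at -0.54 ± 0.092 and -0.60 ± 0.14. Mmp3, a matrix-degrading protease, was at -0.77 ± 0.13 and Ephb3, an ephrin receptor, at -0.88 ± 0.22. Fah, Dglucy, Gab1 and Prkab1 lay between -0.42 and -0.52. These genes did not pass either.

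**Figure D1:**
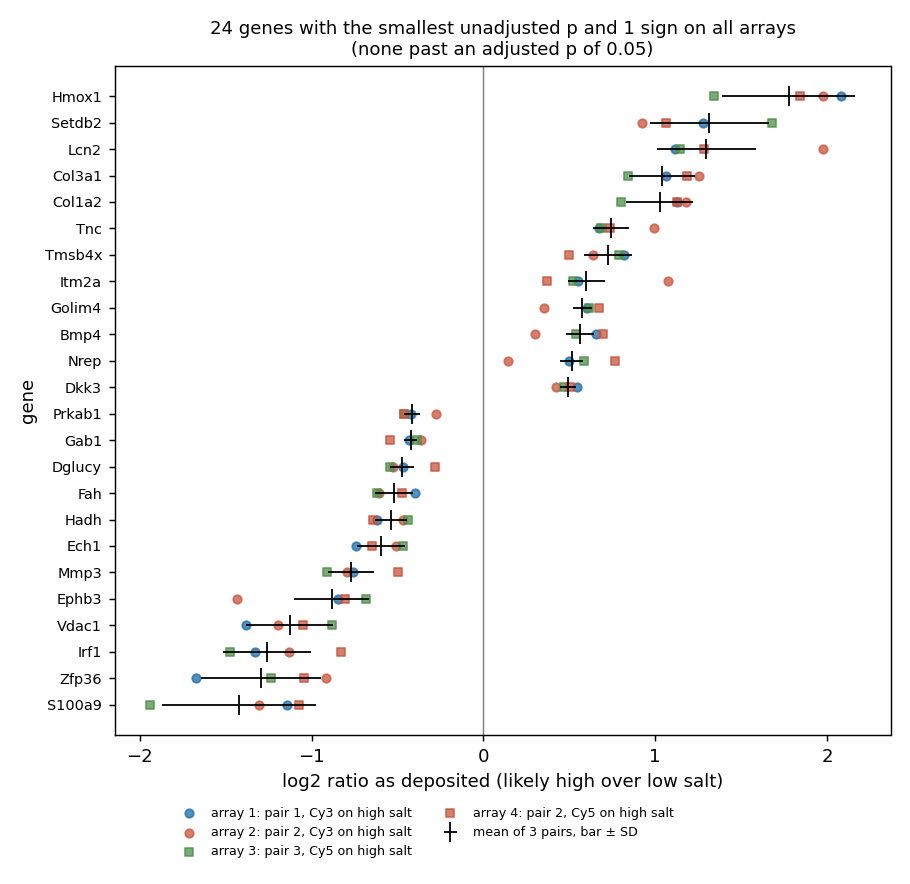
Log2 ratios as deposited (likely high over low salt) of the 24 genes with the smallest unadjusted p and 1 sign on all arrays. Points are the 4 arrays, coloured by animal pair and shaped by dye orientation, and black marks with bars are the mean ± SD of the 3 pairs. Values run from 1.78 for Hmox1 to -1.42 for S100a9, and no gene passed an adjusted p of 0.05.

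Across all genes, limma called 0 of 8106 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.64, shared by all 24 genes above. At an unadjusted p under 0.05, 228 genes were higher and 213 lower, 5.44% of the genes tested. The nominal share without any change is 5%. In simulated data the same fit put 1.66% of unchanged genes there with the measured dye effects and 4.74% without them. The measured dye effects already hold noise, and salt if the table was not turned, and arrays 2 and 4 were given independent noise. The 1.66% is therefore not a null rate for these data. The same test called 0 of 16471 clones, with 464 higher and 394 lower at an unadjusted p under 0.05. With the arrays turned, 0 genes and 0 clones passed as well, while 565 genes were higher and 1118 lower at an unadjusted p under 0.05. A fit of the 3 pairs with a dye covariate, added after seeing the data, also called 0 genes for salt, with 643 higher and 545 lower at the unadjusted threshold. Its dye term, which would hold the effect of salt if the table was not turned, passed for 416 genes. Leaving out pair 2 left 145 genes at an unadjusted p under 0.05, and leaving out pair 3 gave 851, against 441 with all pairs. Without pair 3 the dye orientations are unbalanced, so a dye effect can add to that count. In simulated data with the measured dye effects, the 3-pair fit called 39 of 67 genes changed by 1 on the log2 scale and 0 of 67 changed by 0.5.

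Clones of 1 gene did not always give 1 value. The 4 clones of Col3a1 ranged from 0.014 to 1.98 and the 3 clones of Col1a2 from 0.0058 to 1.60, so the gene means average strong and flat clones. Golim4 had 2 clones at 0.14 and 1.01. The mean values of both clones of Vdac1, at -1.20 and -1.05, and of the 3 clones of Tnc, from 0.51 to 1.10, lay closer together. Between pairs they could still differ. One Tnc clone stood at 1.01, 0.92 and -0.06 in pairs 1 to 3 and another at 0.03, 0.46 and 1.03. Their SDs were 0.59 and 0.50, that of the third 0.12 and that of the gene 0.11. The 2 Dkk3 clones had SDs of 0.28 and 0.35, against 0.047 for the gene. A small SD of such a gene partly comes from averaging unlike clones.

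Of 24 lists, 10 passed an adjusted p of 0.05 by camera with the preset correlation, 5 higher and 5 lower in high salt. None passed with an estimated correlation, where the smallest adjusted p was 0.282, and none by fry for a shift in 1 direction, where it was 0.131, while 9 of the 24 passed fry's test for change in either direction. In simulated data the estimated correlation also missed a list truly shifted by 0.3. That simulation drew the noise of each gene independently, so it cannot show whether the preset correlation calls too many lists. Among the 10 called lists the estimated correlation ran from -0.015 for fibroblast markers to 0.17 for oxidative phosphorylation, against the preset 0.01. With arrays 1 and 2 turned, the means of the 5 higher lists became -0.14 for matrix, -0.08 for fibroblast markers, -0.07 for cell cycle, -0.14 for corticosteroid-responsive and -0.07 for hypertrophy genes. Those of the 5 lower lists became 0.0071 for oxidative phosphorylation, -0.06 for fatty acid, 0.06 for tricarboxylic acid cycle, -0.18 for glycolysis and 0.06 for inflammation genes.

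As a list, matrix genes lay above 0. Of 44 measured collagen and matrix genes, 35 were higher and 9 lower, and 20 were higher on all 4 arrays. With arrays 1 and 2 turned, 16 were higher and 28 lower, with a mean of -0.14 ± 0.31. As deposited, the mean log2 ratio was 0.33 ± 0.18 (SD, n = 3 pairs; camera adjusted p = 4.61e-10, and adjusted p = 0.282 with an estimated correlation). No member passed over all genes, and 9 passed adjusted over the list alone, 8 of them higher. The 4 members with the smallest p were Col3a1, Col1a2, Tnc and, in the other direction, Mmp3. Col1a1 itself, the other chain of type I collagen, had 1 clone at 0.06 ± 0.15, and its sign turned when pair 2 was taken from the array with Cy3 on high salt (-0.15) or when pair 3 was left out (-0.03).

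Fibroblast markers also lay above 0 as a list, and they share 7 genes with the matrix list. Of 13 measured, 11 were higher, the mean was 0.39 ± 0.12 (SD, n = 3 pairs; camera adjusted p = 3.2e-07, and adjusted p = 0.282 with an estimated correlation) and 4 passed adjusted over the list alone. Vim, the intermediate filament of mesenchymal cells, stood at 0.81 ± 0.21 and Fstl1, a secreted glycoprotein, at 0.43 ± 0.14. Without the shared genes the 6 remaining members had a mean of 0.23 (adjusted p = 0.029), a check added after seeing the data.

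The cell cycle list lay above 0, with 24 of 30 members higher. Its mean log2 ratio was 0.20 ± 0.070 (SD, n = 3 pairs). Camera gave an adjusted p of 1.15e-07, and of 0.282 with an estimated correlation. Cdk1, the kinase that drives entry into mitosis, was at 0.54 ± 0.13, Tacc3, a spindle protein, at 0.51 ± 0.18, Ccna2, cyclin A2, at 0.46 ± 0.18 and Tk1, a thymidine kinase of DNA synthesis, at 0.44 ± 0.14, or 0.27 with pair 2 taken from the array with Cy5 on high salt. None of the members passed, over all genes or adjusted over the list alone.

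The list of corticosteroid-responsive and sodium-handling genes lay above 0, with 13 of 18 members higher. Its mean was 0.41 ± 0.16 (SD, n = 3 pairs). Camera gave an adjusted p of 4.37e-05, and of 0.282 with an estimated correlation. Lcn2 and Fkbp5, a glucocorticoid-induced cochaperone of steroid receptors at 1.43 ± 0.54, passed adjusted over the list alone, and 0 passed over all genes. Mt1, a metal-binding metallothionein, stood at 0.89 ± 0.39 and Klf9, a steroid-induced transcription factor, at 0.71 ± 0.47, or 0.43 without pair 1. Sgk1, the kinase through which aldosterone acts on sodium channels, was at 0.47 ± 0.65, at 0.15 without pair 3 and 0.80 without pair 1, and did not have 1 sign on all arrays. Without the 5 members found in other lists the mean was 0.21 and the list no longer passed (adjusted p = 0.072).

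The hypertrophy and fetal gene list was higher, with 10 of 14 members above 0 and a mean of 0.12 ± 0.043 (SD, n = 3 pairs; camera adjusted p = 0.019, and adjusted p = 0.453 with an estimated correlation). Fhl1, a LIM protein of the stretched sarcomere, stood at 0.36 ± 0.17, Igf1, a growth factor, at 0.26 ± 0.13 and Nkx2-5, a cardiac transcription factor, at -0.32 ± 0.17, and none of the members passed over all genes or adjusted over the list alone. Nppb, the natriuretic peptide raised in loaded ventricles, varied between pairs, at 0.35 ± 1.19, and turned to -0.32 without pair 3. The list lost its call without pair 1 (adjusted p = 0.144) or pair 2 (adjusted p = 0.067), with pair 2 taken from the array with Cy5 on high salt (adjusted p = 0.072), with a dye covariate (adjusted p = 0.061) and, at an adjusted p of 0.052, without members shared with other lists. In that order its mean was 0.098, 0.12, 0.080, 0.12 and 0.12.

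Mitochondrial energy genes lay below 0 as lists. Of 65 oxidative phosphorylation genes 53 were lower, with a mean log2 ratio of -0.13 ± 0.088 (SD, n = 3 pairs; camera adjusted p = 3.82e-08, and adjusted p = 0.453 with an estimated correlation). With arrays 1 and 2 turned, 35 were lower and the mean was 0.0071 ± 0.088. As deposited, Ndufa12 of complex I stood at -0.39 ± 0.059 and Sdha of complex II at -0.38 ± 0.12, and without pair 2 the list mean was -0.08. The 3 Sdha clones had SDs of 0.45, 0.50 and 0.60, so the smaller SD of the gene partly comes from averaging unlike clones. On arrays 2 and 4 Ndufa12 stood at -0.67 and -0.24 and Sdha at -0.75 and -0.07. Of 28 fatty acid genes 23 were lower, with a mean of -0.16 ± 0.099 (camera adjusted p = 1.07e-05, and adjusted p = 0.282 with an estimated correlation), and of these Hadh and Ech1 passed adjusted over the list alone. Of 18 tricarboxylic acid cycle genes 16 were lower, with a mean of -0.16 ± 0.025 (camera adjusted p = 1.26e-05, and adjusted p = 0.391 with an estimated correlation), among them Mdh2 at -0.21 ± 0.060 and Fh1 at -0.27 ± 0.13. That SD hides a difference between arrays 2 and 4 of pair 2, where the cycle list stood at -0.32 and -0.04. With pair 2 taken from the array with Cy5 on high salt its mean was -0.12. No member of these 3 lists passed over all genes, and none of the oxidative phosphorylation or cycle genes passed adjusted over the list alone.

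The glycolysis list passed with a small mean of -0.06 ± 0.27 (SD, n = 3 pairs; camera adjusted p = 0.026, and adjusted p = 0.488 with an estimated correlation), with 16 of 20 members lower. None of its members passed over all genes or adjusted over the list alone. Hk2, a hexokinase, stood at -0.22 ± 0.049, or -0.14 with pair 2 taken from the array with Cy5 on high salt, and Pfkp, a phosphofructokinase, at 0.64 ± 0.35. Its mean was 0.07 without pair 3 and it was not called there (adjusted p = 0.785), nor without pair 2 (adjusted p = 0.067), with scaled arrays (adjusted p = 0.066), with pair 2 from the array with Cy5 on high salt (adjusted p = 0.165) or with a dye covariate (adjusted p = 0.056).

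The inflammation and interferon list lay below 0, with 13 of 18 members lower. Its mean was -0.36 ± 0.28 (SD, n = 3 pairs). Camera gave an adjusted p of 0.00069, and of 0.443 with an estimated correlation. Il6, an inflammatory cytokine, was at -0.67 ± 0.40 and Cxcl10, an interferon-induced chemokine, at -0.26 ± 0.054, or -0.16 with pair 2 taken from the array with Cy5 on high salt. Adjusted over the list alone 2 members passed, Irf1 downward and Lcn2 upward, and 0 passed over all genes. The difference was smaller in pair 2, at -0.05, than in pair 1, at -0.60, and pair 3, at -0.42, and without pair 1 the list mean was -0.24.

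**Figure D2:**
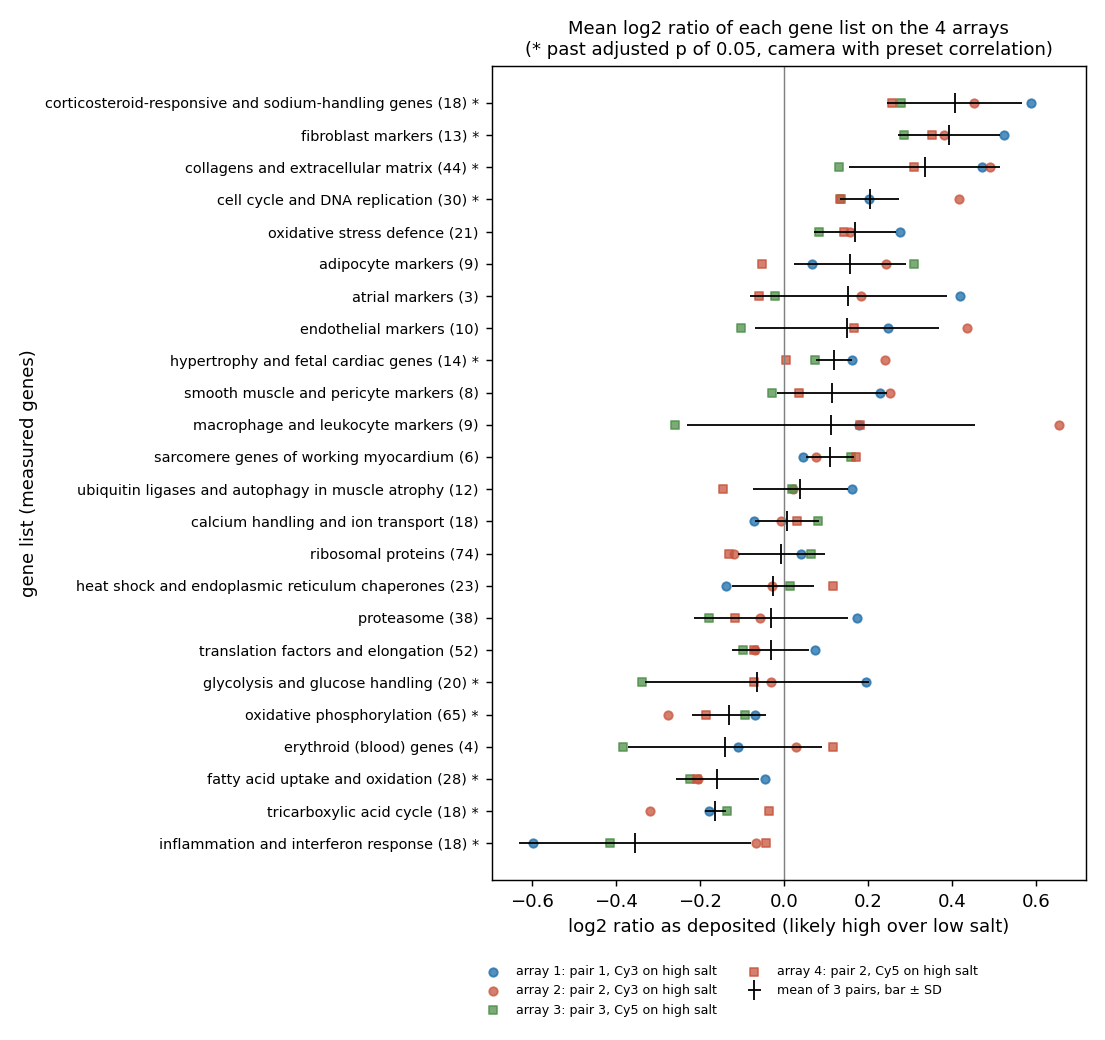
Mean log2 ratio (likely high over low salt) of 24 gene lists, with the number of measured genes in parentheses. Points are the 4 arrays, coloured by pair and shaped by dye orientation, and black marks with bars are the mean ± SD of 3 pairs. The matrix list lies above 0 on all 4 arrays, from 0.13 to 0.49, and the fatty acid list below 0, from -0.22 to -0.04.

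The other 14 lists did not pass. Sarcomere genes had a mean of 0.11 ± 0.058 (SD, n = 3 pairs, 6 genes), led by Fhl2 at 0.68 ± 0.36, calcium handling 0.01 ± 0.075, and oxidative stress defence 0.17 ± 0.098, with Hmox1 past the threshold adjusted over the list alone. Fabp4, a fatty acid-binding protein of fat and capillaries, at 0.37 ± 0.075 passed adjusted over the adipocyte list alone, and Dkk3 over the atrial list alone. Ribosomal proteins (-0.01 ± 0.10), translation factors (-0.03 ± 0.092), proteasome (-0.03 ± 0.18), muscle atrophy (0.04 ± 0.11) and chaperone genes (-0.03 ± 0.098) were near 0. Markers of endothelium stood at 0.15 ± 0.22, smooth muscle and pericytes at 0.11 ± 0.13, macrophages and leukocytes at 0.11 ± 0.34, adipocytes at 0.16 ± 0.13, atrium at 0.15 ± 0.23 and blood at -0.14 ± 0.23. Leaving out a pair moved these means, and without pair 1 or pair 3 a dye effect does not cancel. Such shifts are then not a measure of animals alone. Endothelium was at 0.07 without pair 2 and 0.27 without pair 3, smooth muscle at 0.06 without pair 1 and macrophages at -0.041 without pair 2. Adipocytes were at 0.08 without pair 3, atrium at 0.020 without pair 1 and 0.24 without pair 3, and blood at -0.25 without pair 2 and -0.019 without pair 3. Without pair 3, smooth muscle (0.19, adjusted p = 0.038), macrophage (0.30, adjusted p = 0.0037) and ribosomal lists (-0.04, adjusted p = 0.005) passed, and without pair 1 the proteasome list did (-0.13, adjusted p = 0.023).

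Arrays of 1 dye orientation were more alike than arrays of the same mice. Across 16471 clones, which are not independent replicates, arrays of 1 dye orientation but different mice correlated at r = 0.57 (arrays 1 and 2) and 0.43 (arrays 3 and 4). Arrays 2 and 4, the same 2 mice with exchanged dyes, correlated at -0.07, and the other opposite arrays at -0.08, -0.34 and -0.37. The SD of the difference was 0.488 between arrays 2 and 4, against 0.365 and 0.339 within 1 orientation. With the within-pair correlation set to 0.5, a dye coefficient passed for 474 clones, 169 positive and 305 negative. With no block it passed for 0 clones, with 3434 at an unadjusted p under 0.05, and with a dye covariate on 3 pairs for 0 clones, with 3527. Over genes the covariate called 416, 50 positive and 366 negative. If the table was not turned, these dye terms hold the effect of salt.

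Another 736 features at 23 print positions, which recur in all 32 blocks without a gene name, entered no comparison. At 18 positions the median over blocks exceeded 1 in size on an array, and at 13 of these it changed sign with the dye orientation.

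**Figure D3:**
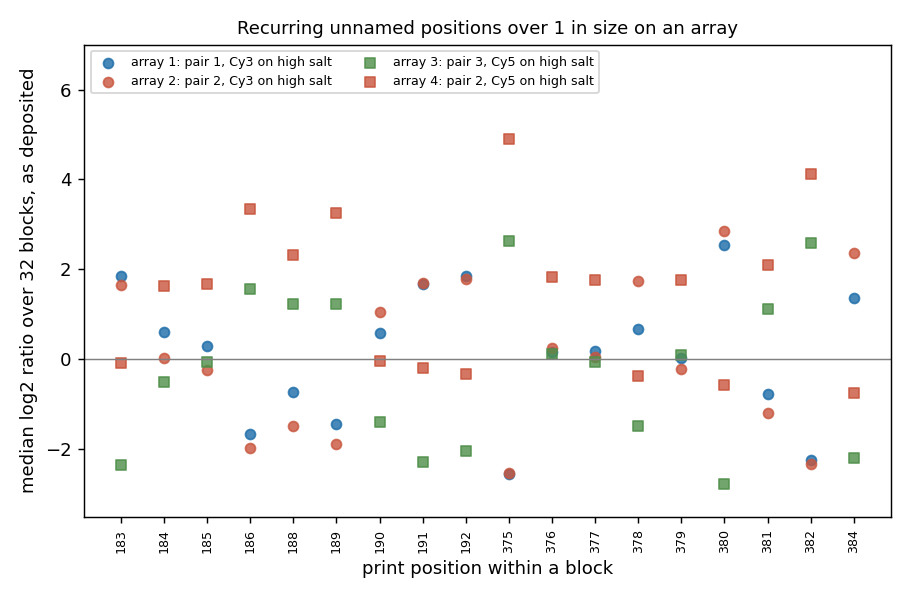
Median log2 ratio over the 32 print blocks, as deposited, at the 18 recurring unnamed positions that exceeded 1 in size, by print position within a block; points are the 4 arrays, coloured by pair and shaped by dye orientation. At 13 positions the sign changed between orientations, with medians from -2.78 to 4.90.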

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

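The tests of this part were chosen after the result was seen. The recurring unnamed features, which enter no comparison, carried strong signal. At 18 of 23 print positions the median over the 32 blocks exceeded 1 in size on at least 1 array, and 13 of these changed sign with the dye orientation, while 1 kept its sign on all arrays. Their block medians ran from -2.78 to 4.90, with a mean SD between blocks of 0.31.

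Clones also had opposite signs on arrays of opposite dye, at r between -0.37 and -0.07. One candidate explanation is that the table holds dye ratios that were never turned, in which case the opposite signs are the salt effect. Its test asked for a negative correlation of the difference between arrays 2 and 1 with that between arrays 4 and 3. This was 0.0502 (SE 0.018) across genes. The test also asked for more lists in the turned reading, where 0 passed against 10 as deposited. Both values lie on the side against it, but as deposited 0 lists passed with an estimated correlation or by fry in 1 direction. The list counts cannot decide. In a table not turned, a dye effect shared by a list's genes would also pass as deposited and cancel when turned. Gene counts run the other way, with 1683 genes at an unadjusted limma p under 0.05 turned against 441 as deposited. A dye effect in a table already turned would raise the turned count too. The SE takes genes as independent, and the requirement that all 4 sets of features give 1 answer was added after the values were seen. Over all features the correlation was -0.0071 (SE 0.011). For the clones the other candidate explanation is a dye effect in a table already turned, which no test here separated from salt. For the recurring positions it is control RNA added by dye to a table already turned. That needs sign changes as at the 13 positions, but control RNA added by salt group to a table not turned gives the same 13. The correlations of clones leave these positions out, so control RNA there does not enter them. The explanations cannot be told apart and the direction stays open.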

How the results depend on the processing

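The fits with a dye term, the return of unnamed features and the lists without shared members were chosen after seeing the data. Under each alternative run, 0 genes and 0 clones passed by limma for the salt term. The turned reading was not combined with a dye term. If the table was not turned, the dye terms of the fits as deposited hold the effect of salt. They passed for 416 genes with the covariate and 474 clones with the set correlation, and for 0 clones with the covariate or no block. Genes at an unadjusted p under 0.05 ranged from 145 to 851 with a pair left out, against 441 with all pairs. They numbered 1683 in the other reading of the table, 1188 with a dye covariate, 818 on 4 arrays with the set correlation and 1050 with no block. The planned fit with an estimated block correlation could not be run, and the rule on missing values removed no clone. The 10 called lists fell to 0 in the other reading, to 0 with an estimated correlation and to 0 by fry in 1 direction. Of all 24 lists, 9 passed fry in either direction. They included the uncalled calcium handling, oxidative stress and atrial lists, and left out called ones such as oxidative phosphorylation (fry adjusted p = 0.168). With a pair left out, 8 to 12 lists were called. Under the 9 camera settings that keep this reading and the preset correlation, 8 of the 10 lists stayed past the threshold and 9 kept their sign. With a pair left out, the list means that turned ranged as follows: glycolysis and glucose handling -0.20 to 0.072, calcium handling and ion transport -0.030 to 0.046, ribosomal proteins -0.042 to 0.053, translation factors and elongation -0.084 to 0.0014, proteasome -0.13 to 0.044, ubiquitin ligases and autophagy in muscle atrophy -0.022 to 0.089, heat shock and endoplasmic reticulum chaperones -0.062 to 0.029 and macrophage and leukocyte markers -0.041 to 0.30. Of the 106 genes named by the rule, 97 kept 1 sign under 11 alternatives that keep this reading, 9 turned, and 0 passed. All 24 chosen by p kept their sign, but they had been chosen for 1 sign on all 4 arrays. These alternatives average, shift or rescale the same arrays, so that outcome was all but fixed by the choice and adds no support. With a pair left out, the log2 ratios of genes that turned ranged as follows: Nppb -0.32 to 0.80, Col1a1 -0.030 to 0.11, Alas2 -0.038 to 0.060, Stard10 -0.44 to 0.31, Pdlim5 -0.033 to 0.24, Pam -0.096 to 0.029, Mylk -0.13 to 0.026 and Car2 -0.90 to 0.18. Values that turned with scaled arrays were Alas2 -0.014 and Stard10 0.041, with pair 2 from the Cy3 array Col1a1 -0.15, Stard10 0.16, Pdlim5 -0.082 and Hba-x 0.027, and from the Cy5 array Alas2 -0.061. The dye count of 474 clones was 0 with no block and 0 with a dye covariate. The correlation of arrays 2 and 4 moved from -0.07 to -0.41 with all features. For these shifts the cause was not tested. The difference in cardiac weight index stayed between 0.76 and 0.83 mg/g with a pair left out.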

Other observations

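The tests of the matrix pattern and of corticosteroid action were chosen after their results were seen, as were the clock and immediate-early lists and the genes named from them. The criteria for the other list members, a sign shared by all 3 pairs, were set before the values of those members were seen. With 3 pairs such a criterion is a weak bar, which values without any shift can also meet.

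Egr1, a zinc finger transcription factor and immediate-early gene, which responds within minutes to stimuli, had a mean log2 ratio of -2.30 ± 1.00 (SD, n = 3 pairs). Other immediate-early genes stood at -1.14 ± 0.49 for Atf3, -0.99 ± 0.71 for Junb (-0.59 without pair 3), -0.91 ± 0.36 for Ppp1r15a and -0.73 ± 0.40 for Fos. Each was below 0 on all 4 arrays as deposited, with limma adjusted p from 0.776 to 0.863, so none passed, and with arrays 1 and 2 turned their means lay between -0.40 for Junb and 0.33 for Egr1. The 16 list members not seen before had a mean of -0.155 (SE 0.0934 over 3 pairs), below 0 in each pair, at -0.34, -0.05 and -0.07, which met the criterion set beforehand, but with arrays 1 and 2 turned the pairs stood at 0.34, 0.08 and -0.07, which does not meet it. The mean lay within 2 SE of 0, 6 of the 16 were higher, and camera gave an adjusted p of 0.074 over 3 added lists and of 0.468 with an estimated correlation, so the list did not pass.

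Matrix genes were higher and mitochondrial genes lower, if the table is read as already turned. A dye effect equal on all arrays cancels in the mean of both orientations. There the matrix list stood at 0.335 (SE 0.104 over 3 pairs) and oxidative phosphorylation at -0.132 (SE 0.051). Each lay beyond 2 SE of 0 and had 1 sign on all 4 arrays, but with 3 pairs 2 SE is a weak bar. For a shift in 1 direction fry gave unadjusted p of 0.043 and 0.148, and adjusted p of 0.148 and 0.318. A mean of 0, which such a dye effect alone would give, is therefore not excluded. A lower share of cardiomyocytes cannot be told apart: the sarcomere mean exceeded the oxidative phosphorylation mean by 0.241 (SE 0.070 over 3 pairs), but without Fhl2 by 0.128 (SE 0.109), within 2 SE of 0, and the 6 fibroblast markers outside the matrix list exceeded endothelial markers by 0.078 (SE 0.082) and smooth muscle ones by 0.11 (SE 0.018). Salt intake, more fibroblasts and more matrix expression per fibroblast also stay open and were not tested apart.

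Clock genes lay on opposite sides of 0, with Ciart at 1.18 ± 0.39 and Arntl at -0.87 ± 0.42 (SD, n = 3 pairs), both of 1 sign on all arrays and neither past the threshold, while with arrays 1 and 2 turned they stood at -0.08 and 0.14. If the table is read as already turned, hearts of the 2 groups may have been at a different clock phase. Leaving out both genes, the 5 Dbp and Per phase genes exceeded the 3 Arntl phase genes by 0.384 (SE 0.177) and in each pair, by 0.73, 0.16 and 0.26, as this needs, whereas with arrays 1 and 2 turned the pairs stood at -0.73, -0.04 and 0.26. As deposited, all 5 Dbp and Per phase genes were above 0, but so were 2 of the 3 Arntl phase genes. The means of those 3 in the pairs were -0.19, -0.04 and 0.04, so the difference came mainly from the Dbp and Per phase genes. By camera the Dbp and Per phase genes passed with the preset correlation (adjusted p = 0.0014) and not with an estimated one (adjusted p = 0.331), and the Arntl phase genes did not pass (adjusted p = 0.379). Corticosteroid action on shared targets cannot be told apart from a different clock phase. It needs the corticosteroid-responsive list without shared clock targets above 0 in each pair. As deposited those 17 genes stood at 0.55, 0.35 and 0.27. It also needs Arntl phase genes that are not below 0, and without Arntl these had a mean of -0.0637 (SE 0.065), which does not decide. The labels give no hour of tissue collection.

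The 4 ways of exchanging the 2 mice within pairs are too few for a share under 0.05. The counts of 0 genes and 0 clones were reached in all 4, with 0 as the highest other. For genes at an unadjusted p under 0.05 the count was 441 and the highest other 999, from exchanging the mice of pair 3, and 2 of the 4 gave as many as 441. That exchange sets pairs 1 and 3 in line by dye orientation, which points to a structure of the arrays; it is the dye in this reading and salt if the table was not turned, and no test separates these. For gene lists the count was 10 and the highest other 6, and 1 of the 4 gave as many.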
